A study of Mus musculus with 4 samples.

How the data were processed

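Liver RNA was sequenced from wild-type (WT) mice and from mice in which Fto was knocked out (KO), with 2 libraries per genotype. Per the labels, the animals were C57BL/6 mice of 23 weeks, RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo-dT beads, RNA integrity was checked on a Bioanalyzer, libraries were made with the TruSeq v2 kit, and paired reads of 101 bases were read on a HiSeq3000. That kit does not mark the strand, so reads from a gene and from an overlapping antisense gene cannot be told apart. Selection for polyadenylated RNA leaves out most histone and other RNAs without a tail.

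The deposited files hold 1 whole-number count of reads per Ensembl gene, not normalised. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with TopHat2 2.1.1 and counted with HTSeq 0.6.0. The annotation release and the counting options are not given in the sources used here. Counting of this kind drops reads that match several genes, so members of near-identical families (the major urinary proteins, the Cyp2a and Cyp2b enzymes, the Ugt2b enzymes, the carboxylesterases, Selenbp2 with its close paralog, and the alpha-1-antitrypsin genes) have uncertain levels. The files hold 37315 gene identifiers. GENCODE release M21, which is built on the same assembly, gave a symbol and a position for 35449 of them, and 1866 had no match. The unmatched identifiers held between 0.143% and 0.194% of the counts of a library. No row without a gene identifier was present, and no column of another sample was used.

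The libraries held 41332870 and 39549592 counts for WT replicates 1 and 2, and 44689114 and 40947808 counts for KO replicates 1 and 2. At this depth 1 read corresponded to between 0.0224 and 0.0253 counts-per-million (CPM). No pair of libraries agreed within sampling noise: the chi-square statistic per degree of freedom was between 86.5 and 226.03 over genes with at least 20 counts in a pair, so each library was used as 1 replicate.

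From the deposited counts, differences between genotypes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 13836 genes. Library sizes were scaled with TMM, dispersions and the quasi-likelihood fit were estimated with the robust option, and KO was compared with WT by the two-sided quasi-likelihood F test with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the size of the log2 fold change divided by the square root of F. Levels are CPM after TMM scaling, as mean ± SD over the 2 libraries of a genotype. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

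The test, the gene lists, the rule for naming genes and the other settings were fixed before the data were examined. A total of 48 lists of genes (liver pathways, stress responses, sex-biased liver genes, RNA methylation, neighbours of Fto and markers of cell types) were fixed, and the 47 with at least 4 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Fto left out of every list. Camera with an estimated correlation and the rotation test fry were run beside it. The pancreas acinar list was left out with 2 tested members. The rule for naming genes took Fto and its listed neighbours, the 12 largest increases and the 12 largest decreases among called protein-coding genes with a mean of at least 2 CPM and an assigned name, genes of the sex chromosomes, and up to 4 members with the smallest p from each list described. Further members of those lists are named where a count of called members was small or where they complete a group; these, and all genes named outside the lists, were chosen after their values were seen.

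Positions are from GENCODE M21, counted from 1. Transcript length is that of the longest annotated transcript. The whole procedure was tested on simulated counts drawn from the means and library sizes of these libraries for KO against WT, with 13593 genes per run, 5 runs and 200 genes changed. It recovered 52.8% of 2-fold changes and 97.2% of 4-fold changes, with 4.50% false calls. The changed genes were drawn from those with a mean of at least 1 CPM. In the same runs the circadian clock list was shifted up by 1 on the log2 scale. It was called in 5 of 5 with the preset correlation and in 0 of 5 with an estimated correlation. Smaller shifts of a list were not simulated. Genes were drawn independently of each other, with the dispersion trend alone and no effect of replicate number or length. The real libraries differ in this, so these rates may not hold for them.

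The alternatives were DESeq2 size factors or library size alone in place of TMM, no filter on low counts or a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the robust option switched off, each library left out in turn, a term for the replicate number, and an added threshold of 1 on the log2 fold change. With 1 library left out, the lone library of its genotype was assumed to vary like those of the other genotype.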

Results

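Gene expression in the liver was compared between WT mice and mice lacking Fto, which encodes a dioxygenase that removes methyl groups from RNA, N6-methyladenosine (m6A) among them. The data are RNA-seq counts for 2 WT and 2 KO libraries, and the comparison of the genotypes asks which transcripts differ in the liver when Fto is disrupted. Total counts were 41332870 and 39549592 in the WT libraries and 44689114 and 40947808 in the KO libraries. Between 18758 and 19267 genes had at least 1 read in a library. Over the tested genes, log2 levels of the WT libraries correlated with r = 0.983 and those of the KO libraries with r = 0.985, and pairs of different genotype with r of at least 0.966; these correlations are across genes, which are not independent replicates. Transcripts encoded by mitochondrial DNA made up 7.25% and 7.52% of the counts of the WT libraries and 5.81% and 7.49% of those of the KO libraries.

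The libraries numbered 2 differed from those numbered 1 in the same way in both genotypes. Among protein-coding genes with a longest transcript under 1000 bases, the median log2 ratio of replicate 2 over replicate 1 was 0.36 in WT and 0.18 in KO. Among genes with a transcript over 8000 bases it was -0.49 in WT and -0.45 in KO. The KO over WT ratio varied less with length, from a median log2 fold change of -0.12 in the shortest class to 0.12 in the longest. Each number holds 1 WT and 1 KO library, so no test within a number was possible.

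**Figure D1:**
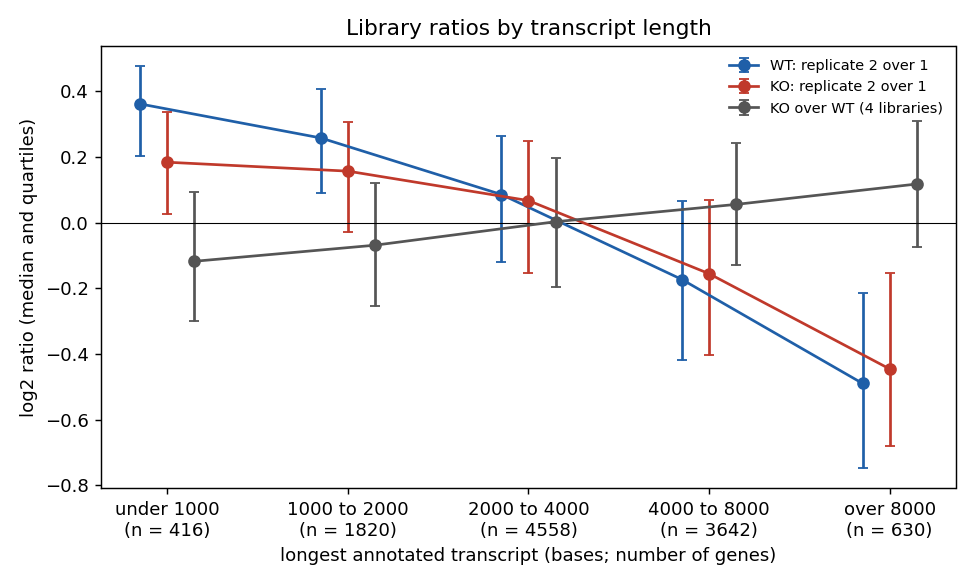
Median log2 ratio (vertical axis, bars from the lower to the upper quartile over genes) by class of longest transcript length in bases (horizontal axis) for replicate 2 over 1 in WT, replicate 2 over 1 in KO, and KO over WT. The replicate ratios fall from 0.36 and 0.18 in the shortest class to -0.49 and -0.45 in the longest, while the KO over WT ratio runs from -0.12 to 0.12.

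Fto itself was lower in both KO libraries. It fell by 1.57 on the log2 scale (log2 fold change -1.57, SE 0.195, adjusted p = 0.0109, edgeR quasi-likelihood test), from 37.6 ± 5.16 CPM in WT to 12.6 ± 0.697 CPM in KO (SD, n = 2 each). The WT libraries held 1749 and 1292 Fto reads and the KO libraries 607 and 486. The KO level was 33.6% of WT in the fit, 31.8% between the libraries numbered 1 and 35.8% between those numbered 2. The counts cover the whole gene (chromosome 8, 91313525 to 91668439, plus strand, mm10), so they do not show which exons the reads remaining in KO came from.

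With genotype as the only term, none of the 6 tested neighbours on the fixed list was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 with edgeR. Rpgrip1l, which starts from the opposite strand beside Fto and has a part in cilia, had a log2 fold change of -0.28 (SE 0.304, adjusted p = 0.789), and Aktip one of -0.22 (SE 0.194, adjusted p = 0.718). The chromatin remodeller Chd9 had 0.53 (SE 0.230, adjusted p = 0.392). Rbl2 had 0.07, Lpcat2 0.19 and Mmp2 -0.01, each within its SE of 0; the signs of these last 3 changed when some single libraries were left out. Irx3, a homeobox gene regulated from within Fto introns in other tissues, had 17 and 3 reads in WT and 2 and 2 in KO and was too low to test, as were Irx5, Irx6, Crnde, Slc6a2 and Tox3. Farther out, 10 of the 137 other genes tested within 10 Mb of Fto were called, against 1.85% of tested genes elsewhere, a window set after the values were seen. Over all 276 windows of 10 Mb in the genome, that from 80 to 90 Mb of chromosome 8 (7 of 87 genes called), which does not hold Fto itself, did not pass (adjusted p = 0.125). The 10 genes were Mt1, Mt2, Ces1g, Zfp423, Gpt2, Klf1, Fbxw9, Gadd45gip1 and Mri1, all lower in KO, and Cacna1a, which was higher. The call of Gpt2 was lost without KO replicate 1 (adjusted p = 0.0815) and that of Mri1 without KO replicate 2 (adjusted p = 0.0562) and with library size alone (0.101).

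**Figure D2:**
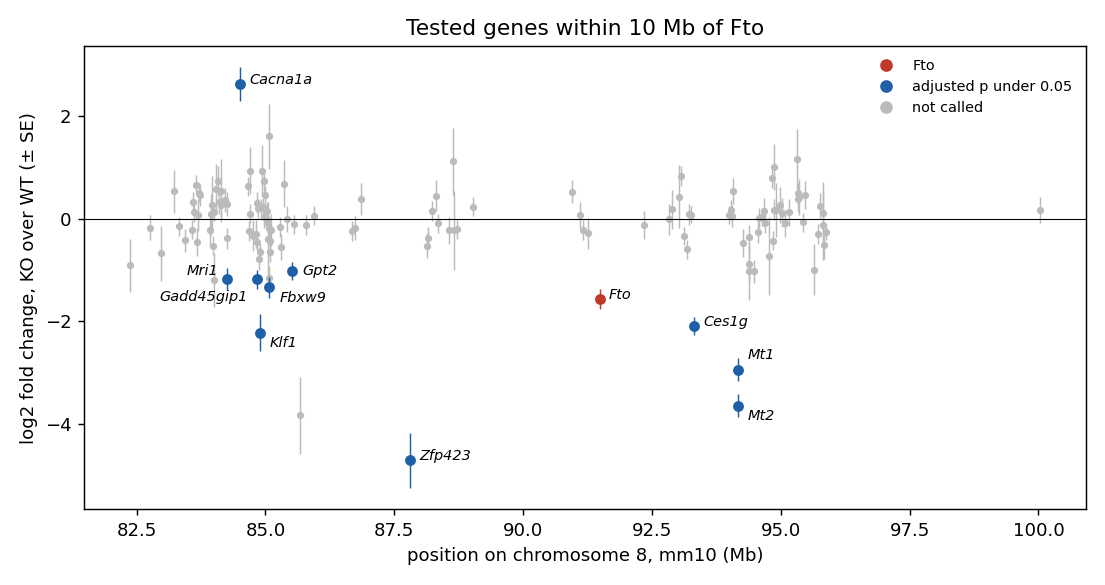
Log2 fold change of KO over WT with its SE (vertical axis) against position on chromosome 8 in Mb (horizontal axis, mm10) for all tested genes within 10 Mb of Fto. Besides Fto at -1.57, 10 genes are called, 9 of them lower in KO.

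All 4 libraries carried transcripts of the Y chromosome. Ddx3y was at 46.2 ± 0.409 CPM in WT and 50.6 ± 2.68 CPM in KO (SD, n = 2 each), and its log2 fold change of 0.13 did not pass (adjusted p = 0.847). The log2 fold changes of Eif2s3y, Kdm5d and Uty were 0.12, -0.06 and 0.18, and none passed. Xist, which is transcribed from the inactive X of females, had between 3 and 6 reads per library.

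Among protein-coding genes with a mean of at least 2 CPM, the largest decreases in KO liver included the lipid droplet gene Cidea, the triglyceride synthesis gene Mogat1 and the P450 genes Cyp2b9 and Cyp2a4, and the largest increases Selenbp2, Enho, Asns and Cd207. Of 13836 genes tested, 264 (1.91%) were called by edgeR, 133 higher and 131 lower in KO, with absolute log2 fold changes of at least 0.91; 254 of them changed by at least 1 on the log2 scale. All 264 had the same sign within number 1 and within number 2, which their selection by the genotype test largely sets. At an unadjusted p under 0.05 there were 1800 genes. Leaving out a library raised the count to 633 without WT replicate 1, 521 without WT replicate 2, 460 without KO replicate 1 and 513 without KO replicate 2. It was 829 with no filter on low counts and 559 with DESeq2, and scaling by library size alone gave 176, 93 higher and 83 lower. A term for the replicate number gave 2729, but the labels do not say that equal numbers pair animals.

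Selenbp2, which encodes a cytosolic selenium-binding protein of liver, had the smallest p of the increases. It rose 16.6-fold, from 39.5 ± 0.694 to 655 ± 11.2 CPM (SD, n = 2 each; log2 fold change 4.05, SE 0.185, adjusted p = 4.74e-04). Enho, which encodes the secreted peptide adropin, rose 12.6-fold from 2.21 ± 0.256 to 27.9 ± 2.30 CPM (adjusted p = 0.0011). The glucuronosyltransferase gene Ugt2b38 rose 12.3-fold and the asparagine synthetase gene Asns 11.6-fold. Cd207, which encodes the lectin langerin of Langerhans and some dendritic cells, rose 11.5-fold, from 0.892 ± 0.261 to 10.2 ± 0.563 CPM. The adhesion receptor gene Adgrf1 rose 14.1-fold, the collagen chain gene Col5a2 7.10-fold, and the calpain gene Capn8 6.71-fold. Moxd1, a monooxygenase-like gene, had 1 and 2 reads in WT and 659 and 303 in KO, a ratio of 302.9 with a 95% exact interval from 103.3 to 1471 that covers counting error only; its log2 fold change of 8.08 became 8.68 without WT replicate 2. Fabp5, a fatty acid binding protein, Derl3, a factor of endoplasmic reticulum (ER) protein disposal, and the major urinary protein gene Mup8 rose by log2 fold changes of 3.48, 3.07 and 3.02, with KO libraries that differed widely. Without KO replicate 2 these were 2.32, 2.39 and 2.12. Fabp5 was 4.12 without KO replicate 1 and lost its call without WT replicate 2 (adjusted p = 0.455). Fabp5 and Mup8 were not called with library size alone (adjusted p = 0.0661 and 0.0585), nor Fabp5 without the filter on low counts (0.552). Col5a2 rose by 3.54 on the log2 scale without WT replicate 2.

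Cyp2b9, a cytochrome P450 of female-biased expression, had the largest decrease with a mean of at least 2 CPM. It fell from 125 ± 54.8 to 1.57 ± 0.0119 CPM (SD, n = 2 each; log2 fold change -6.31, SE 0.376, adjusted p = 0.0011). Cidea, a lipid droplet protein, fell from 36.7 ± 8.46 to 0.562 ± 0.336 CPM (log2 fold change -6.05, SE 0.403, adjusted p = 0.00115). Mogat1, an acyltransferase of triglyceride synthesis, fell from 9.91 ± 3.30 to 0.196 ± 0.0293 CPM (log2 fold change -5.63). Mt2, a metallothionein that binds zinc and copper, fell from 26.0 ± 1.55 to 2.08 ± 0.343 CPM, and Cdkn1a, the cell cycle inhibitor p21, from 11.9 ± 2.31 to 1.06 ± 0.0916 CPM. The orphan receptor gene Gprc5b, the T cell signalling gene Themis, the neurotrophin receptor gene Ntrk2 and the peroxisomal transporter gene Abcd2 fell by log2 fold changes of -4.49, -3.93, -3.83 and -3.70. The P450 gene Cyp2a4, the organic anion transporter gene Slc22a27 and the sulfotransferase gene Gal3st1 had -4.06, -3.37 and -3.04. With library size alone none of these 3 was called (adjusted p = 0.0511, 0.0511 and 0.0922), and with limma-voom Cyp2a4 and Slc22a27 were not (0.0728 and 0.0684). Their values depended on single libraries: without WT replicate 2, Cyp2a4 was -2.83 and Slc22a27 -2.51; without WT replicate 1, Cyp2a4 was -4.72; Gal3st1 was -2.29 without KO replicate 1 and -4.49 without KO replicate 2; and Cidea was -6.82 without KO replicate 2.

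**Figure D3:**
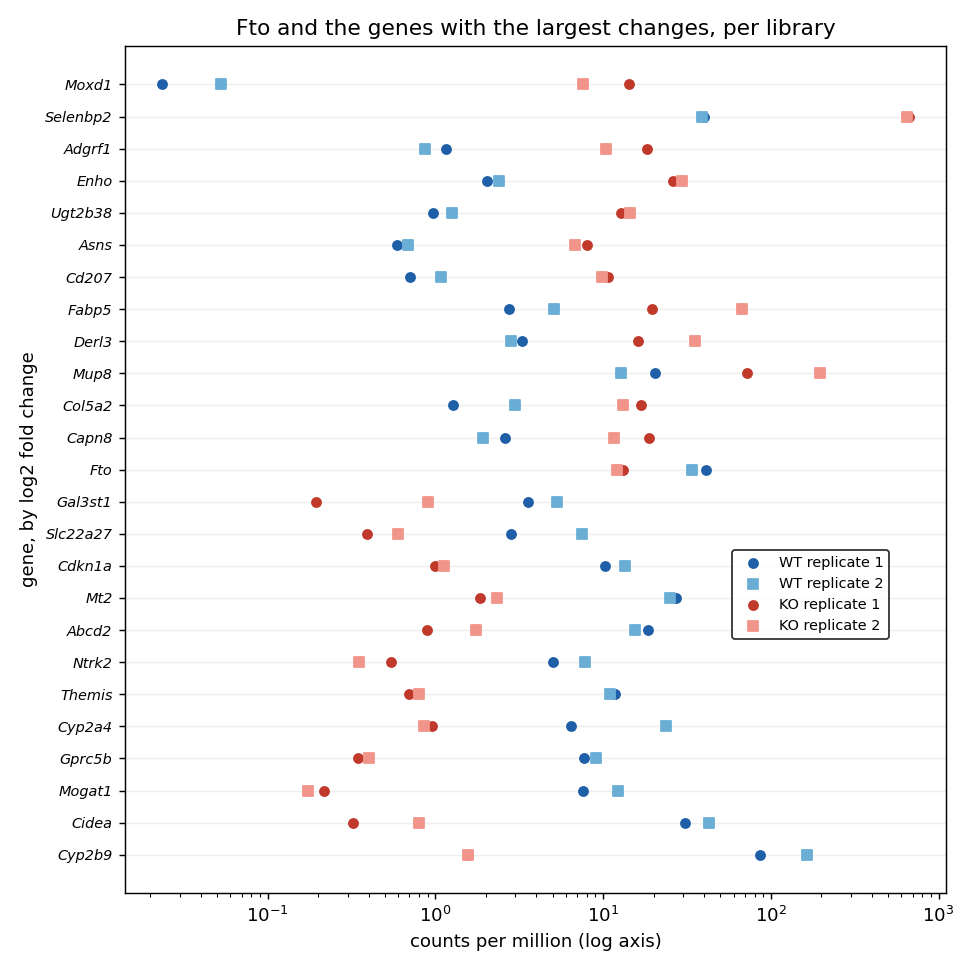
Level in each of the 4 libraries in CPM (horizontal log axis, each point 1 library) for Fto and the 24 genes with the largest increases and decreases at a mean of at least 2 CPM (vertical axis, ordered by log2 fold change). The genes were picked for this difference, as for Selenbp2 with 39.5 CPM in WT and 655 CPM in KO.

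Among the 47 gene lists tested by camera with a preset correlation, 20 were called, 7 up and 13 down. None was called with an estimated correlation, where the smallest adjusted p was 0.715 and 2 lists had an unadjusted p under 0.05. In simulated data with independent genes that setting found a shifted list in 0 of 5 runs. The directional fry test called 1 list, that of male-biased genes, and gave the other 19 adjusted p from 0.0693 to 0.642. Its mixed test called 21.

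Male-biased liver genes rose and female-biased liver genes fell as lists. Of 27 tested male-biased genes 10 were higher and 1 lower, with 16 higher and 3 lower when adjusted over the list alone, and the median log2 fold change was 1.01 (camera adjusted p = 9.15e-08, 0.715 with an estimated correlation, 0.0308 with fry). Besides Selenbp2 and Ugt2b38, these included Cyp7b1, an oxysterol hydroxylase (log2 fold change 1.60, adjusted p = 0.00564), the antitrypsin gene Serpina1e (2.40, adjusted p = 0.00719) and the complement genes C6 (1.52) and C8b (1.34). The lower gene was the carboxylesterase Ces2e (-1.01), whose call was lost without WT replicate 2 (adjusted p = 0.0511). Of 20 tested female-biased genes 7 were lower and 1 higher, with 8 lower and 2 higher when adjusted over the list alone, and the median was -0.53 (camera adjusted p = 1.94e-04, 0.715 with an estimated correlation, 0.227 with fry). The lower genes were Cyp2b9, Cyp2b13, Cyp2a4, the hydroxyacid oxidase Hao2, the thioesterase Acot3 (-1.91), the sulfotransferase Sult2a7 (-2.90) and the nuclear factor Tox (-1.43; adjusted p = 0.0805 with library size alone). Hao2 had 132 and 148 reads in WT and 1 and 2 in KO, a ratio of WT over KO of 98.8 with a 95% exact counting interval from 33.5 to 482.1; its log2 fold change of -6.53 became -7.16 without KO replicate 2. The higher gene was the estrogen sulfotransferase Sult1e1 (4.08, adjusted p = 0.00384). On the list of the insulin and growth hormone axis, which was not called (adjusted p = 0.143, median -0.003 and mean 0.40, which differ in sign), Enho, the receptor gene Egfr (1.93) and the feedback inhibitor Socs2 (2.06; adjusted p = 0.0511 with library size alone) rose.

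Lists of lipid droplets and lipolysis and of fatty acid oxidation fell. Of 17 tested genes of lipid droplets and lipolysis 4 were lower and none higher (6 lower when adjusted over the list alone), namely Cidea, Mogat1, the perilipin Plin4 (-1.81) and Fitm1 (-1.07), and the median log2 fold change was -0.47 (camera adjusted p = 1.84e-05, 0.715 with an estimated correlation). The call of Fitm1 was lost without WT replicate 2 (adjusted p = 0.0572) and with library size alone (0.0649). Of 32 genes of fatty acid oxidation and targets of PPARα, a receptor that is activated by fatty acids, 5 were lower and 1 higher (11 lower and 2 higher when adjusted over the list alone), with a median of -0.37 (adjusted p = 1.25e-05, 0.715 with an estimated correlation). The lower genes were the fatty acid transporter Cd36 (-2.25, adjusted p = 0.00323), the thioesterases Acot3 and Acot2 (-1.91 and -1.29), the peroxisomal thiolase Acaa1b (-1.29) and the pantetheinase Vnn1 (-1.51), and the higher gene was the fatty acid hydroxylase Cyp4a31 (adjusted p = 0.0434). Acot2 lost its call without KO replicate 2 (adjusted p = 0.0512) and Cyp4a31 without WT replicate 2 (adjusted p = 0.0603), and both with library size alone (0.103 and 0.0717). Of 25 genes of fatty acid and triglyceride synthesis 2 were lower, the desaturase Scd1, which fell from 11186 ± 2479 to 3530 ± 1072 CPM (SD, n = 2 each; adjusted p = 0.0245), and the malic enzyme Me1 (-1.43), and 5 when adjusted over the list alone. This list (median -0.18, adjusted p = 0.00976, 0.751 with an estimated correlation) lost its call without WT replicate 2 (adjusted p = 0.307) and without KO replicate 2 (0.0768). The adipocyte marker list also fell (median -0.47 over 9 genes, adjusted p = 0.0186, 0.751 with an estimated correlation), with Pparg, the regulator of fat cell genes, lower (-1.31; adjusted p = 0.0607 with library size alone), and lost its call without WT replicate 2 (adjusted p = 0.498) and without KO replicate 1 (0.488). On that list the fat cell genes Adipoq, which encodes adiponectin, and Lep, which encodes leptin, both picked after their values were seen, had reads almost only in the libraries numbered 2. Adipoq had 1 and 70 reads in WT replicates 1 and 2 and 0 and 71 in KO, and Lep had 0 and 41 in WT and 0 and 36 in KO. Neither was called, but Lep was called in opposite directions without WT replicate 2 (log2 fold change 7.26, adjusted p = 0.0342) and without KO replicate 2 (-7.49, adjusted p = 0.0169).

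Genes of cholesterol synthesis and uptake rose as a list. Of 25 genes on it 1 was higher, the squalene epoxidase Sqle (log2 fold change 1.83, adjusted p = 0.0144), and 6 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.00109, 0.751 with an estimated correlation); the call was lost without WT replicate 1 (adjusted p = 0.112). Of 25 genes of bile acid synthesis and transport 3 were higher, Cyp7a1, the rate-limiting enzyme of the classic pathway (37.1 ± 2.48 to 120.2 ± 19.0 CPM, adjusted p = 0.00802), Cyp7b1 and Cyp39a1 (1.18; adjusted p = 0.0794 with library size alone), and 4 higher and 4 lower when adjusted over the list alone. That list was not called (adjusted p = 0.581): its median was -0.11 and camera gave down, while its mean was 0.02 and fry gave up. Of 21 genes of lipoproteins and lipid export, Apom (1.18) and the lipase gene Lpl (1.43) were higher. Lpl was not called with library size alone (adjusted p = 0.0528). Adjusted over the list alone, 2 were higher and 2 lower. The lower ones were Pltp (-1.36) and Apoc1 (-0.63), neither called over all genes. The list was not called (adjusted p = 0.283), and its median was -0.27 with camera giving down.

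Markers of Kupffer cells, the macrophages of the liver, were higher in KO. All 16 had a positive log2 fold change (median 0.90, camera adjusted p = 5.19e-10, 0.715 with an estimated correlation). The median KO over WT log2 ratio was 1.14 within number 1 and 0.67 within number 2. The markers also moved together within WT, each higher in replicate 2 than in replicate 1, as Cd5l with 58.2 against 34.5 CPM. They are therefore not independent observations, and the preset correlation of 0.01 may be too low for them. The scavenger receptor Marco (1.66, adjusted p = 0.0155) and the receptor Csf1r (0.97, adjusted p = 0.0478) were called, and all 16 were higher when adjusted over the list alone. Csf1r lost its call without WT replicate 1 (adjusted p = 0.067), without KO replicate 1 (0.0842) and with library size alone (0.0738). The marker list of stellate cells and fibroblasts fell (median -0.30 over 16 genes, adjusted p = 0.0121, 0.751 with an estimated correlation) and lost its call without WT replicate 2 (adjusted p = 0.310) and without KO replicate 2 (0.150). No gene of it was called by edgeR, DESeq2 or limma-voom, and 3 had an unadjusted p under 0.05 with edgeR. Markers of red blood cells fell as a list (median -0.71 over 7 genes, adjusted p = 0.00785, 0.715 with an estimated correlation), and not without WT replicate 2 (adjusted p = 0.151). EdgeR called 0 of these genes, with 5 at an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. Adjusted over the list alone, 4 were lower, all of them globin genes, and 1 was higher, Tfrc (0.65). Marker lists of hepatocytes (median 0.12, adjusted p = 0.217), endothelial cells (-0.02, 0.581), cholangiocytes (0.08, 0.830), T and natural killer cells (0.26, 0.304), B and plasma cells (-0.02, 0.683), neutrophils (0.36, 0.522), mesothelial and smooth muscle cells (-0.25, 0.134) and intestinal and gallbladder epithelium (-0.42, 0.371) were not called.

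Lists of ER chaperones, heat shock and acute phase genes were called up, and lists of p53 targets, proliferation, antioxidant and drug metabolism genes down. Of 20 ER chaperones and unfolded protein response genes, 19 had a positive log2 fold change and Creld2, an ER stress gene, was called (0.99, adjusted p = 0.0345), with a list median of 0.42 (camera adjusted p = 1.21e-04, 0.715 with an estimated correlation). Heat shock genes rose as a list (median 0.39 over 16 genes, adjusted p = 9.30e-04, 0.715 with an estimated correlation), with Hspb1 called (1.67). Acute phase genes rose as a list (median 0.38 over 27, adjusted p = 9.40e-04, 0.751 with an estimated correlation), with the interleukin receptor Il1r1 (1.31) and the signalling inhibitor Socs3 (1.40; adjusted p = 0.0669 with library size alone) called, and not without KO replicate 2 (adjusted p = 0.273). Of 21 genes of the integrated stress response edgeR called Asns alone and DESeq2 called 2, and that list was not called (adjusted p = 0.304). Of 16 targets of p53, Cdkn1a and the receptor gene Eda2r (-2.21; adjusted p = 0.0677 with library size alone) were lower, 8 were lower when adjusted over the list alone, and the median was -0.54 (adjusted p = 1.25e-05, 0.715 with an estimated correlation). Of 24 proliferation genes 19 had a negative log2 fold change and the marker of cycling cells Mki67 was called (-1.99, adjusted p = 0.0478; 0.0629 with limma-voom and 0.0807 with library size alone), with a median of -0.62 (adjusted p = 1.25e-05, 0.715 with an estimated correlation). Of 21 antioxidant genes on the NRF2 list, the metallothioneins Mt2 and Mt1 (-2.94) and the glutathione transferase Gsta2 (-1.16; adjusted p = 0.0677 with library size alone) were lower (median -0.29, adjusted p = 3.67e-04, 0.715 with an estimated correlation). Of 24 drug metabolism genes under CAR and PXR, nuclear receptors that sense xenobiotics, Cyp2b10 was lower (-3.51, and -4.25 without KO replicate 1; list median -0.24, adjusted p = 0.00311, 0.751 with an estimated correlation), and the list lost its call without WT replicate 2 (adjusted p = 0.310) and without KO replicate 1 (0.0626). Of 21 immediate early genes, Gadd45g (-1.81), Nr4a1 (-2.10) and Dusp1 (-1.11) were lower, while the list was not called (adjusted p = 0.683). With library size alone, Nr4a1 and Dusp1 were not called (adjusted p = 0.0598 and 0.0669).

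Lists of ribosomal proteins and of oxidative phosphorylation were called with small shifts and no called member. All 52 tested cytosolic ribosomal protein genes had a positive log2 fold change, between 0.01 and 0.49 with a median of 0.23 (camera adjusted p = 2.05e-04, 0.786 with an estimated correlation). All 42 nuclear genes of oxidative phosphorylation had a negative one, between -0.32 and -0.03 with a median of -0.16 (adjusted p = 0.0136, 0.796 with an estimated correlation). No gene of either list was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 with edgeR. These are mostly short transcripts, with a median length of 1114.5 and 1231.5 bases. For transcripts of 1000 to 2000 bases, the median log2 ratio of replicate 2 over 1 was 0.26 in WT and 0.16 in KO, and that of KO over WT was -0.07. After a fitted trend of fold change with transcript length and GC content was removed, the ribosomal median was 0.27 and that of oxidative phosphorylation -0.11. The ribosomal list lost its call without WT replicate 1 (adjusted p = 0.407) and without KO replicate 2 (0.123), and the oxidative phosphorylation list without KO replicate 1 (adjusted p = 0.490) and, with its direction reversed, without WT replicate 2 (0.958). Genes of glycolysis and glycogen fell as a list (median -0.35 over 22, adjusted p = 0.00589, 0.786 with an estimated correlation) and not without WT replicate 2 (adjusted p = 0.450) or KO replicate 1 (0.0632). No gene of it was called by edgeR over all genes, with 7 at an unadjusted p under 0.05. Pfkfb3, among those 7, was higher in KO (0.72). Adjusted over the list alone, 1 gene was higher and 1 lower. DESeq2 called 2 and limma-voom 1.

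Genes of the m6A machinery other than Fto gave no call with genotype as the only term. None of 23 tested writers, readers and erasers was called by edgeR over all genes or when adjusted over the list alone, nor by DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 with edgeR. Their log2 fold changes lay between -0.53 (Mettl5, adjusted p = 0.371) and 0.47 (the methyltransferase Mettl3, adjusted p = 0.397), and the list was not called (adjusted p = 0.567). The list of other 2-oxoglutarate dioxygenases, the enzyme family of Fto, was not called either (20 genes, median 0.08, adjusted p = 0.566). Lists without a call also included the circadian clock (adjusted p = 0.581), interferon response (0.830; camera down, mean 0.04), gluconeogenesis (0.283, with the alanine transaminase Gpt2 lower), amino acid catabolism and the urea cycle (0.116), one-carbon metabolism (0.134, with the methyltransferase Bhmt lower by edgeR), extracellular matrix (0.190, with Col5a2 higher), AhR targets (0.352) and mitochondrially encoded mRNAs (0.212). Pericentral hepatocyte genes (0.174, with the transporter Slc1a4 lower) and periportal ones (0.709; median 0.01, mean -0.04) were not called, nor were the neighbours of Fto (0.931) or the Y-linked genes (0.683). The call of Bhmt was lost without WT replicate 2 (adjusted p = 0.0879) and without KO replicate 1 (0.0808).

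**Figure D4:**
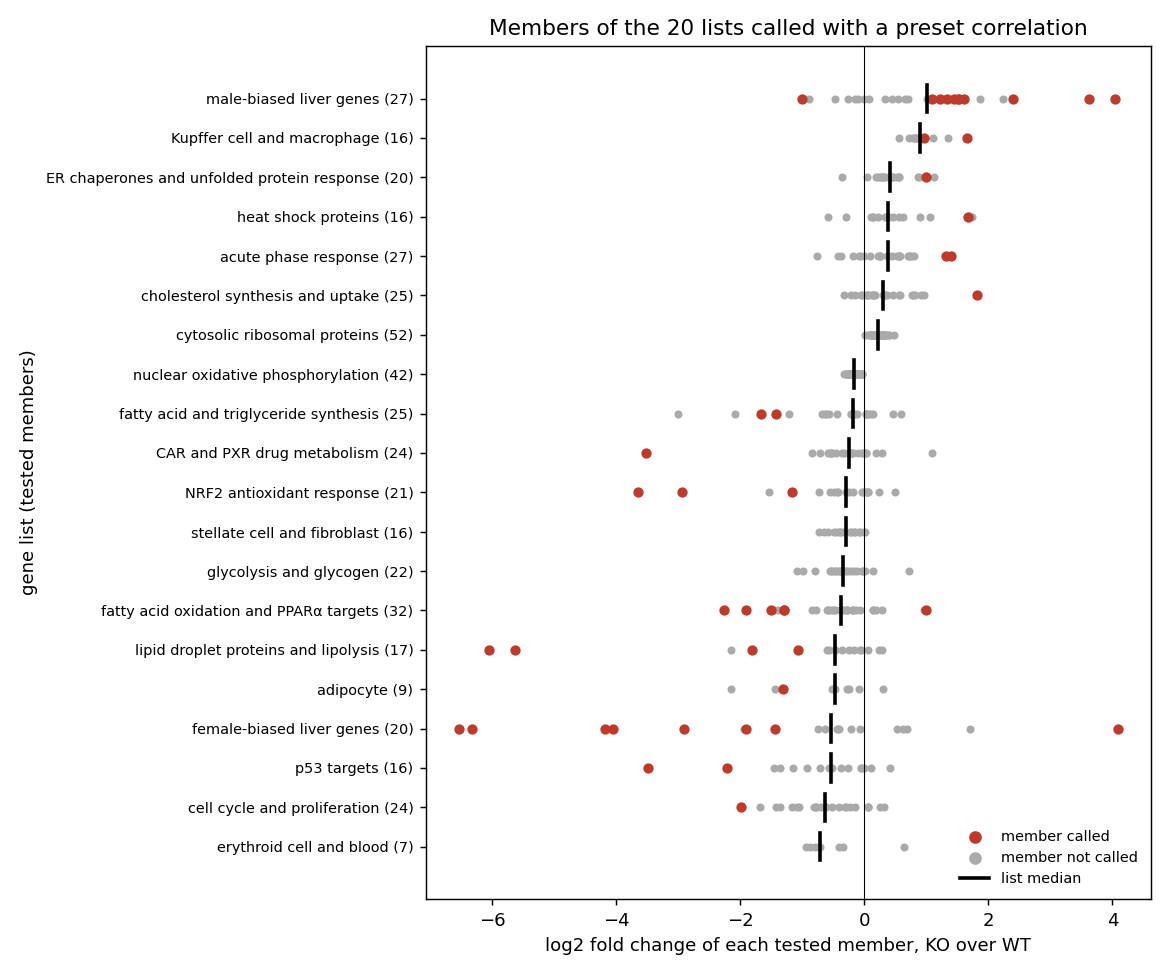
Log2 fold change of KO over WT for each tested member (points; horizontal axis) of the 20 called lists (vertical axis, with the number of tested members), with members called over all genes in red and the list median as a black bar. Medians run from -0.71 for red blood cell markers to 1.01 for male-biased genes, and the female-biased list holds both Cyp2b9 at -6.31 and Sult1e1 at 4.08.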

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

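The sets of 2 libraries limit the analysis. In simulations of independent genes, 52.8% of 2-fold changes were recovered among changed genes with a mean of at least 1 CPM. A gene without a call may therefore still differ. Fto was called in every alternative, with a log2 fold change between -1.72 and -1.43 when single libraries were left out. All 264 called genes kept their sign in each alternative that tested them, which their selection by the genotype test on the same libraries largely sets. DESeq2 kept all 264, the fit without a filter 263, limma-voom 245 and library size alone 175. The count of called genes was 829 with no filter (435 higher, 394 lower), 559 with DESeq2 (279 and 280), between 460 and 633 with 1 library left out (231 to 341 higher, 229 to 292 lower), and 176 with library size alone (93 and 83); the cause was not tested. Samples with the same number deviated together across genes (correlation 0.427), but the labels say neither that the numbers pair animals nor that they mark a batch. With the replicate number as a term (a replicate block), 2729 genes were called, 1404 higher and 1325 lower, 258 of the 264 among them, and 20 lists were called. Chd9, Mettl5 and Mettl3 were then called at 0.54, -0.53 and 0.47, and Derl3, Mup8 and Cyp2a4 were not. Library size alone ended the calls of Fabp5, Mup8, Cyp2a4, Slc22a27 and Gal3st1 among the largest changes and of list members named with the results, limma-voom those of Cyp2a4, Slc22a27 and Mki67, and no filter that of Fabp5. Uncalled genes near 0 changed sign: Mmp2 was 0.0125 with library size alone, and with a library left out Mmp2 ran from -0.096 to 0.074, Rbl2 from -0.20 to 0.40, Lpcat2 from -0.14 to 0.58, Eif2s3y from -0.19 to 0.37, and Kdm5d from -0.17 to 0.030. Adipoq ran from -8.28 to 5.05 without a call, and Lep from -7.49 to 7.26 with calls at both ends (adjusted p = 0.0169 and 0.0342). The number of called lists was 0 with an estimated correlation and 1 with fry, and the oxidative phosphorylation list reversed without WT replicate 2 (adjusted p from 1.07e-04 to 0.958 with a library left out); the cause was not tested.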

Other observations

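The genes in this and the next paragraph were chosen after their values were seen. Meg3, an imprinted long noncoding RNA, rose from 1.87 ± 0.477 CPM in WT to 24.8 ± 5.23 CPM in KO (SD, n = 2 each; log2 fold change 3.73, edgeR adjusted p = 0.00132). The leukemia inhibitory factor receptor gene Lifr rose from 199.7 ± 0.214 to 501.3 ± 38.2 CPM (adjusted p = 0.0118), and the leptin receptor gene Lepr from 0.742 ± 0.084 to 4.34 ± 0.132 CPM (adjusted p = 0.00739). Scara5, a ferritin receptor, rose from 2.80 ± 0.243 to 18.0 ± 0.0999 CPM (adjusted p = 0.00135).

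Raet1d and Raet1e, ligands of the activating receptor of natural killer cells, fell by log2 fold changes of -2.38 and -3.03 (edgeR adjusted p = 0.00598 and 0.00719), while the T and natural killer cell markers were not called. They lie on chromosome 10 between 20 and 30 Mb, where 5 of 36 tested genes were called, among them Moxd1, Themis and Vnn1 (adjusted p over 276 windows = 0.0782). Of those windows, 1 passed, between 60 and 70 Mb of chromosome 4, where the major urinary protein genes lie (12 of 58 called, adjusted p = 2.05e-07). Apart from Gm13775, its called genes were members or pseudogenes of that family, whose levels are uncertain. The test counted them as separate genes, so its p overstates the evidence for a cluster. The zinc finger genes Zfp992, Zfp979 and Zfp982 fell by log2 fold changes of -2.65, -3.01 and -1.14. Nnt, which carries a deletion in the C57BL/6J substrain, fell from 132.3 ± 6.30 to 59.1 ± 11.3 CPM (adjusted p = 0.032), a call that was lost without KO replicate 1 (adjusted p = 0.0581).

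Of the tests that follow, those of length and GC on the male-biased list and of time of day were chosen before their results were seen, and the others after. The male-biased list rose and the female-biased list fell, calls that were lost with an estimated correlation (adjusted p = 0.715 for both). Female animals among the WT libraries would lower Y-linked genes and raise Xist in those libraries. The median log2 fold change of the Y-linked genes was 0.12, against 1.01 for the male-biased list. Ddx3y was at 46.5 and 45.9 CPM in the WT libraries and at 48.7 and 52.5 CPM in the KO libraries. Xist had 6 and 4 reads in WT and 6 and 3 in KO. These values argue against female animals among the WT libraries. Reads shared within multigene families are argued against as the whole source by 4 called genes outside such families (C6, C8b, Hao2 and Tox), out of 15 tested. Each went in the direction of its list, and 0 went the opposite way. That 0 follows from the rule for families, which was set after the values were seen. It left out Ces2e and Sult1e1, the called genes that went against their lists. Removing the trend of fold change with transcript length and GC left the male-biased median at 1.003. Over length classes the median KO over WT ratio ran only from -0.12 to 0.12, so this step could change little. An effect of genotype on these genes stays open and was not tested further.

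Called genes were more frequent within 10 Mb of Fto than elsewhere, though not beside it. By midpoint, the nearest was Ces1g at 1.83 Mb, then Mt2 and Mt1 at 2.68 and 2.69 Mb and Zfp423 at -3.68 Mb. The others, from Mri1 to Gpt2, lay between -7.24 and -5.98 Mb. Of 137 tested genes within 10 Mb, Fto left out, 10 were called where 2.54 would be at the rate elsewhere (one-sided Fisher's exact p = 2.96e-04), and counting each gene family once left p = 6.32e-04, so neighbouring paralogs such as Mt1 and Mt2 do not account for it. A candidate explanation is DNA of another strain or substrain carried along with the Fto allele. It stays open beside an effect of genotype on these genes. The window was set after the values were seen, and no sequence was examined. Over all 276 windows, that from 80 to 90 Mb (7 of 87 called), which does not hold Fto itself, did not pass (adjusted p = 0.125). The 6 listed neighbours were not called with genotype as the only term, though Chd9 was with a replicate block. Zfp423, with 63 and 65 reads in WT and 2 and 3 in KO (ratio of WT over KO 27.1, 95% exact counting interval from 11.3 to 84.9), lies between 87661810 and 87959595 of chromosome 8.

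Longer transcripts read lower in the libraries numbered 2. The rank correlation across 11066 genes of the replicate ratio with length was -0.53 in WT and -0.43 in KO, as a difference in RNA integrity or in coverage along transcripts between the libraries could give; genes are not independent replicates. The rank correlation of the replicate ratio with GC content was -0.037 in WT and -0.23 in KO. This argues against GC content as a source in WT, while a part for it in KO stays open. A difference in time of day is argued against by clock genes, whose median absolute log2 ratio lay at percentile 42.9 in WT and 48.2 in KO among 10000 random lists matched on expression. Integrity itself cannot be measured from counts, and no biological explanation other than time of day was tested.

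The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The genotype split called 264 genes by edgeR, with 1800 at an unadjusted p under 0.05. The highest of the other splits called 0, with 1733 genes at that unadjusted threshold for the split by number and 36 for the crossed one. Of the 3 splits, 1, the genotype split itself, gave as many calls. In the other splits the difference between genotypes counts as spread within groups, which can lower the number of calls. These counts therefore cannot tell an effect of genotype from an accidental grouping.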
